A study of Mus musculus with 18 samples.

How the data were processed

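Total RNA of 18 BMDM samples was sequenced, with 3 libraries for each of 6 groups: Lyz2Cre and Lyz2Cre:KLF6 Fl/Fl, each untreated, with scleroglucan or with HKCA. Per the labels, RNA was taken with a High Pure RNA kit and libraries were made with a TruSeq Stranded Total RNA kit. The submitters' processing notes name STAR, Cufflinks and Cuffdiff, without versions, and the mm10 build. The gene counter, the annotation release, the strand setting, the size-factor tool and the way reads shared between near-identical genes were assigned are not given in the sources used here.

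The single table was taken as deposited, with 1 column per library and 53465 genes. Its signal values were made by the authors as gene read counts divided by 1 size factor per library and rounded to 1 decimal, although the table is named for FPKM, fragments per kilobase of gene scaled to library size. This was checked on the values. The smallest step between low values was the same for short and long genes within a library, which FPKM does not give, and dividing by that step returned whole reads within 0.1 of a read for 100% of low values. The value of 1 read ran from 0.741 to 1.68 between libraries. The design had been written for FPKM, and its pseudocount, filter and comparisons were kept for the scaled counts. Recovered depth was 22.0 M to 33.4 M reads in genes per library, and 19202 to 21662 genes had a read. The sums of the deposited values ran from 21.6 M to 38.0 M, and were highest with HKCA (group means 37.7 M and 36.9 M, against 21.6 M to 24.6 M in the other groups), so other scalings were run beside the deposited one. The 10 most abundant genes took 10.7% to 13.4% of a library. Spread between replicates in reads was above counting error, with a chi-square per degree of freedom of 3.87 to 8.35 outside HKCA-treated Lyz2Cre.

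Gene positions came from GENCODE M21 (GRCm38, the assembly called mm10), in which 53360 of 53465 gene identifiers were found. Symbols are those of the table, and 108 symbols stand on more than 1 line (220 lines), which were kept apart. Genes with a mean value of at least 1 over the 18 libraries were tested, 19440 of 30927 with any read. Values were turned to log2 after adding 1, and a model with 1 mean per group was fitted in limma 3.58.1 (R 4.3.3) with a variance prior that follows abundance (eBayes with trend, 12 residual degrees of freedom, median prior 9.67). In all, 13 comparisons were made: each stimulus against untreated in each genotype and in their mean, HKCA against scleroglucan in Lyz2Cre, the genotypes in each treatment and in the mean of the 3, and the interactions of genotype with each stimulus. A gene passed at a Benjamini-Hochberg adjusted p under 0.05 over all genes tested in a comparison. Standard errors are those of limma, and standard deviations are between 3 libraries. For genes with 10 or fewer reads in a whole group, the group levels are given and no fold, because the fitted fold then depends on the added 1. The interaction of Ifi213 and of Arg1 is the exception, and their levels in untreated Lyz2Cre stand beside it.

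40 gene lists (891 entries) of pathways, cell states and markers of other cells were tested with camera in limma. A correlation of 0.01 between genes was preset, p-values were adjusted over the 40 lists of a comparison, and the test was repeated with a correlation estimated for each list. The comparisons, lists, thresholds and most alternatives were fixed before the data were examined. A filter at a mean of 10 and an edgeR test with TMM factors were added afterwards, and the genes named in the text were picked from the results. The size of a response was compared between genotypes as the median, over genes called in the mean of both genotypes, of the difference in response, with a two-sided permutation of genotype labels within treatments (400 arrangements). Arrangements that leave the stimulated libraries in place carry part of the same difference, so this test can miss a real shortfall, and a p above 0.05 in it does not show equal responses. Klf6 was also compared by an exact permutation test on its values.

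The alternatives were a pseudocount of 0.1, no filter on low values, libraries scaled to a common upper quartile or a common sum, quantile normalisation, eBayes without trend, a fit of only the groups compared, values summed over lines that share a symbol, an edgeR 4.0.16 count test on recovered reads, a list correlation estimated from the data, a fold change of at least 2, the replicate number as a block, and leaving out each library in turn. The number in a replicate's label was not used as a pair in the tests reported, because libraries that share a number were not alike. Over 15 pairs of groups and 10240 genes, 0 had all 3 same-number correlations of residuals above 0.1, and the median was 0.00743.

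The tests were tried on simulated data built from these libraries. With 2 groups of 3, limma recovered 52% of genes changed 1.25-fold, 80% at 1.5-fold, 90% at 2-fold and 96% at 4-fold, and for an interaction 22%, 54%, 80% and 92%, with 8 false calls in each. edgeR recovered 52%, 84%, 92% and 98%, and for an interaction 22%, 60%, 82% and 92%, with 8 and 11 false calls. In camera the shifted list was called and 0 of 39 others were. A simulated response of 70% of the size was found at 70.1% with a permutation p = 0.0700, and an equal response at 100% with a permutation p = 0.0600. The permutation p was thus similar for a smaller and an equal response, while the estimated size was not. Each size was simulated only once, with no difference between the untreated genotypes. These runs therefore cannot show how well the permutation test tells the sizes apart. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 was used for reading, checks and plots. Interaction results of Ccl24 and Cyp1a1 for scleroglucan and of Elfn1 and Timd4 for HKCA, and the mean genotype difference of Cd79b, had been picked to be named and were then left out, because a group held 10 or fewer reads. This was decided after their values were seen, and several of them had lost their call under an alternative. Results of some other genes are not reported here.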

Results

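Total RNA was sequenced from bone marrow-derived macrophages (BMDMs) of C57BL/6 mice at postnatal week 10. There were 2 genotypes and 3 treatments, with 3 libraries in each of the 6 groups, so 18 libraries in all. One genotype was Lyz2Cre alone, and the other carried floxed alleles of Klf6, a Krüppel-like transcription factor, with the same Cre (Lyz2Cre:KLF6 Fl/Fl). Lyz2Cre places the recombinase under a gene active in macrophages and neutrophils. The cells were left untreated, or were given scleroglucan, a fungal beta-glucan, or the stimulus that the labels call HKCA and do not spell out. The doses and times of treatment were not in the labels used here. The series title gives its subject as the part KLF6 plays in the macrophage inflammatory response. Each stimulus was set against untreated cells within a genotype, to ask what it changed. The genotypes were set against each other within a treatment, to ask what the floxed alleles changed, and the difference between these differences (the interaction) asked whether the response depended on genotype. Depth was 22.0 M to 33.4 M reads counted in genes per library, with group means between 25.1 M in untreated Lyz2Cre and 30.5 M in HKCA-treated Lyz2Cre:KLF6 Fl/Fl. All fold changes are log2 values with their standard errors, for 3 libraries per group, and adjusted p-values come from limma. No label places the replicates in separate mice or cultures, so the p-values measure the spread between these libraries.

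Klf6 RNA was lower in Lyz2Cre:KLF6 Fl/Fl than in Lyz2Cre in each treatment, but it was not lost. Klf6 (ENSMUSG00000000078, chromosome 13, 5861482 to 5870394, mm10) averaged 8152 ± 218 normalised counts (SD, n = 3) in untreated Lyz2Cre:KLF6 Fl/Fl and 12214 ± 264 in untreated Lyz2Cre, which is 66.7% of the Lyz2Cre level. With scleroglucan the means were 8159 ± 333 and 13060 ± 206 (62.5%), and with HKCA 23872 ± 398 and 41485 ± 2027 (57.5%). The libraries of the genotypes did not overlap in any treatment (two-sided exact permutation p = 0.1 in each, the smallest that 3 against 3 allows). In limma the Klf6 difference was -0.58 ± 0.04 untreated (adjusted p = 4.3e-10), -0.68 ± 0.04 with scleroglucan (adjusted p = 2.4e-11), -0.80 ± 0.04 with HKCA (adjusted p = 2.0e-12) and -0.69 ± 0.02 over the 3 treatments (adjusted p = 4.6e-16). HKCA raised Klf6 in Lyz2Cre (1.76 ± 0.04) and in Lyz2Cre:KLF6 Fl/Fl (1.55 ± 0.04). Scleroglucan did not change it past the threshold in either genotype (0.10 in Lyz2Cre and 0.00 in Lyz2Cre:KLF6 Fl/Fl). In Lyz2Cre it passed when only these groups were fitted (adjusted p = 0.0288) and in edgeR with TMM factors (adjusted p = 0.0421), with adjusted p up to 0.764 elsewhere. The counts cover the whole gene, and the labels do not give the part flanked by the loxP sites, so the share of recombined alleles cannot be read from them.

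**Figure D1:**
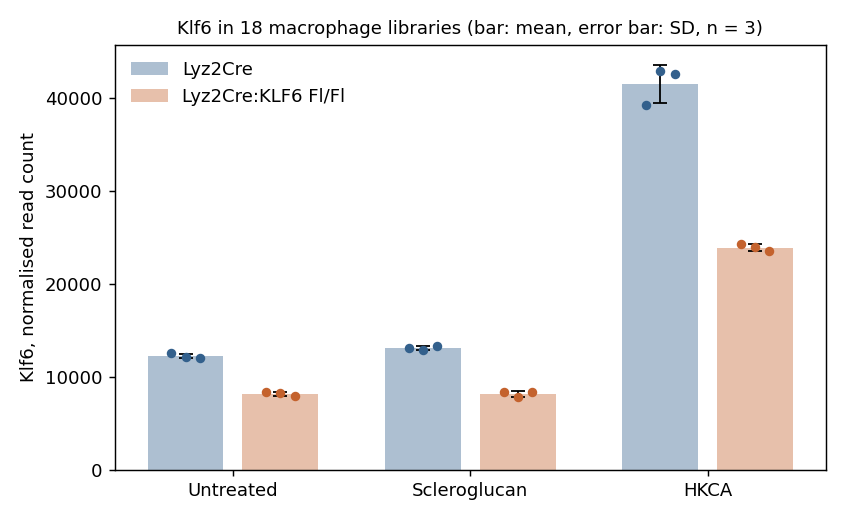
Klf6 in normalised read counts (vertical axis) by treatment (horizontal axis) and genotype (colour). Bars are means of 3 libraries, error bars are 1 SD and points are libraries, and HKCA-treated Lyz2Cre libraries average 41485 and HKCA-treated Lyz2Cre:KLF6 Fl/Fl libraries 23872.

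In Lyz2Cre macrophages given scleroglucan, Olr1, the oxidised low-density lipoprotein receptor, rose from 0.600 ± 0.529 to 1848 ± 186 normalised counts (SD, n = 3), and Tarm1, an activating receptor of myeloid cells, from 1.57 ± 1.16 to 302 ± 24.2. The chemokine genes Cxcl2 (8.86 ± 0.23) and Cxcl3 (6.30 ± 0.22) rose with Acod1, which encodes the itaconate-forming enzyme (7.48 ± 0.18), Clec4e, the C-type lectin receptor Mincle (6.99 ± 0.12), and Gpr84, a receptor for medium-chain fatty acids (6.96 ± 0.19). Large falls were in Dkk2, a secreted Wnt antagonist (-5.30 ± 0.32), Rasgrp3, a Ras activator (-3.99 ± 0.17), the transcription factor gene Zbtb16 (-3.82 ± 0.41), Rspo2, a Wnt enhancer (-3.34 ± 0.17), and Hpgd, which degrades prostaglandins (-3.34 ± 0.30). Of all genes, 8218 of 19440 genes tested passed (4183 higher, 4035 lower). Changes of 2-fold or more accounted for 2292 of them (1490 higher, 802 lower). More genes were lower than higher with a common sum (3517 higher and 5021 lower), a common upper quartile (3964 higher and 4306 lower) and quantile normalisation (3817 higher and 4585 lower), but not in edgeR with TMM factors (4427 higher and 4092 lower).

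Of 40 gene lists, 20 passed in Lyz2Cre with scleroglucan. Among NF-kB feedback and inflammatory cytokine genes, 23 of 30 rose, 0 fell and 7 did not pass (camera adjusted p = 1.8e-20, adjusted p = 0.0148 with an estimated correlation). They included Il1b (5.92 ± 0.38), Ptgs2 (4.93 ± 0.15) and Tnf (3.53 ± 0.07). Of the chemokines, 16 of 23 rose, 3 fell and 4 did not pass (camera adjusted p = 1.7e-07, adjusted p = 0.0148 with an estimated correlation), and Ccl22 was one of them (4.88 ± 0.35). Interleukin-10 and feedback inhibitor genes moved too, as 18 of 21 rose, 2 fell and 1 did not pass (camera adjusted p = 1.3e-12, adjusted p = 0.0244 with an estimated correlation). Il10 rose (2.98 ± 0.15), and so did Il1rn, the interleukin-1 receptor antagonist (4.29 ± 0.06). Targets of NRF2, the transcription factor of the oxidative stress response, moved one way: 17 of 19 rose, 0 fell and 2 did not pass (camera adjusted p = 9.6e-19, adjusted p = 0.0112 with an estimated correlation). They included Slc7a11, a cystine transporter (5.03 ± 0.10), the quinone reductase gene Nqo1 (3.75 ± 0.12) and the haem oxygenase gene Hmox1 (3.53 ± 0.06). Of immediate-early transcription factor and phosphatase genes, 22 of 27 rose, 1 fell and 4 did not pass (camera adjusted p = 1.5e-13, adjusted p = 0.0323 with an estimated correlation). Nr4a3, an orphan nuclear receptor, was one (4.44 ± 0.18). Of matrix remodelling and coagulation genes, 24 of 26 rose, 1 fell and 1 did not pass (camera adjusted p = 1.6e-14, adjusted p = 0.0112 with an estimated correlation). The protease inhibitor gene Serpinb2 (4.89 ± 0.12) and the metalloproteinase gene Mmp19 (3.86 ± 0.07) were among the risers. Adjusted over the list alone, these counts were the same apart from 25 higher and 1 lower in the matrix remodelling list.

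Further lists moved with scleroglucan in Lyz2Cre, but their calls were not kept with an estimated correlation between genes. Type I interferon-stimulated genes went up: 30 of 33 rose, 0 fell and 3 did not pass (camera adjusted p = 1.5e-15, adjusted p = 0.105 with an estimated correlation). Ifit1 (2.86 ± 0.11) and Mx1 (2.80 ± 0.18) were among them. Of glycolysis genes, 17 of 23 rose, 3 fell and 3 did not pass (camera adjusted p = 4.5e-07, adjusted p = 0.101 with an estimated correlation), such as the glucose transporter gene Slc2a1 (1.93 ± 0.06) and the hexokinase gene Hk2 (1.41 ± 0.06). Cholesterol synthesis and uptake genes went down: 2 of 22 rose, 17 fell and 3 did not pass (camera adjusted p = 1.1e-05, adjusted p = 0.104 with an estimated correlation). The synthesis genes Lss (-1.07 ± 0.08) and Dhcr7 (-0.89 ± 0.14) were among them. Of liver X receptor targets and fatty acid synthesis genes, 3 of 20 rose, 11 fell and 6 did not pass (camera adjusted p = 8.1e-04, adjusted p = 0.0662 with an estimated correlation). The desaturase gene Scd2 (-2.17 ± 0.08) and the cholesterol exporter gene Abcg1 (-1.75 ± 0.05) fell. Of S-phase genes, 3 of 25 rose, 12 fell and 10 did not pass (camera adjusted p = 0.0110, adjusted p = 0.225 with an estimated correlation). The replication licensing genes Cdc6 (-1.04 ± 0.28) and Mcm7 (-0.78 ± 0.12) fell, while Cdt1, which acts with them, rose (0.70 ± 0.07). The numbers adjusted over the list alone were the same apart from 4 higher and 13 lower in the liver X receptor list.

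In Lyz2Cre:KLF6 Fl/Fl given scleroglucan, Olr1 rose from 1.07 ± 0.379 to 582 ± 50.5 normalised counts (SD, n = 3). Cxcl2 (5.39 ± 0.23), Gpr84 (5.05 ± 0.19), Clec4e (4.88 ± 0.12) and Acod1 (4.73 ± 0.18) rose with Inhba, which encodes an activin subunit (4.42 ± 0.17). Dkk2 (-3.12 ± 0.32) and Rspo2 (-2.67 ± 0.17) fell. Of all genes, 5780 of 19440 genes tested passed (3068 higher, 2712 lower). At least 2-fold changes made up 1160 of them (785 higher, 375 lower). The majority turned to lower with a common sum (2724 higher and 3302 lower), a common upper quartile (2657 higher and 3311 lower) and quantile normalisation (2904 higher and 3354 lower), but not in edgeR with TMM factors (3789 higher and 2683 lower). Of the 40 lists, 16 passed, NRF2 targets by the lowest p: 18 of 19 rose, 0 fell and 1 did not pass (camera adjusted p = 9.9e-25, adjusted p = 0.00626 with an estimated correlation). Of NF-kB feedback and inflammatory cytokine genes, 21 of 30 rose, 1 fell and 8 did not pass (camera adjusted p = 4.3e-17, adjusted p = 0.0298 with an estimated correlation). Matrix remodelling and coagulation genes rose as well: 19 of 26 rose, 0 fell and 7 did not pass (camera adjusted p = 3.4e-14, adjusted p = 0.00626 with an estimated correlation). Of heat shock and dissociation stress genes, 6 of 12 rose, 0 fell and 6 did not pass (camera adjusted p = 0.00110, adjusted p = 0.0298 with an estimated correlation). These counts were, adjusted over the list alone, the same. Averaged over both genotypes, 9153 genes passed (4641 higher, 4512 lower, against 3959 higher and 5460 lower with a common sum and 4197 higher and 5016 lower with a common upper quartile), and so did 20 lists.

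In Lyz2Cre macrophages given HKCA, the cytokine gene Il1b (14.21 ± 0.38), the chemokine gene Cxcl10 (13.66 ± 0.18) and Nos2, the inducible nitric oxide synthase (12.43 ± 0.32), rose. So did the interferon-induced genes Gbp5 (13.02 ± 0.26), Ifi205 (12.61 ± 0.13) and Mx1 (12.27 ± 0.18), and Acod1 (13.02 ± 0.18). Il6 went from 2.0 ± 2.65 to 9022 ± 726 normalised counts (SD, n = 3), and Il12b, listed at 0 in untreated Lyz2Cre, reached 2434 ± 164. Large falls were in Cnr2, the cannabinoid receptor of immune cells (-7.49 ± 0.23), Rasgrp3 (-6.63 ± 0.17), Bmf, a pro-apoptotic BH3-only gene (-5.75 ± 0.23), and Sesn1, a stress-induced sestrin (-5.16 ± 0.10). Dkk2 fell from 343 ± 6.73 to 3.43 ± 1.94. Mrc1, the mannose receptor of alternatively activated macrophages, did not pass (0.03 ± 0.05), but it did with 3 other scalings, lower in each (-0.11, -1.07 and -0.66 with a common upper quartile, quantile normalisation and a common sum). Of all genes, 12289 of 19440 genes tested passed (6129 higher, 6160 lower). Changes of 2-fold or more accounted for 6303 of them (3318 higher, 2985 lower). With libraries scaled to a common sum the split was 3171 higher and 10931 lower, and the median of all tested genes moved to -0.64, so list directions for HKCA are given only where no scaling turned their median.

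In Lyz2Cre with HKCA, 24 of the 40 lists passed. Interferon-stimulated genes of the type I list rose throughout: 33 of 33 rose, 0 fell and 0 did not pass (camera adjusted p = 2.1e-27, adjusted p = 0.0468 with an estimated correlation). Guanylate-binding protein and immunity-related GTPase genes did as well: 17 of 17 rose, 0 fell and 0 did not pass (camera adjusted p = 3.1e-13, adjusted p = 0.0130 with an estimated correlation). Of NF-kB feedback and inflammatory cytokine genes, 30 of 30 rose, 0 fell and 0 did not pass (camera adjusted p = 1.7e-21, adjusted p = 0.0130 with an estimated correlation). Ptgs2 (10.42 ± 0.15) and Tnf (6.49 ± 0.07) were among them. Of the chemokines, 21 of 23 rose, 1 fell and 1 did not pass (camera adjusted p = 3.4e-11, adjusted p = 0.00728 with an estimated correlation), and Ccl5 was one of the risers (10.23 ± 0.27). Interleukin-10 and feedback inhibitor genes followed, as 20 of 21 rose, 1 fell and 0 did not pass (camera adjusted p = 1.3e-11, adjusted p = 0.0223 with an estimated correlation). Il10 itself rose (8.29 ± 0.15). Of class I presentation genes, 13 of 13 rose, 0 fell and 0 did not pass (camera adjusted p = 5.4e-11, adjusted p = 0.0506 with an estimated correlation), so this call was not kept. The peptide transporter gene Tap1 (5.37 ± 0.08) and the immunoproteasome gene Psmb9 (4.23 ± 0.10) were 2 of them. Of inflammasome genes, 13 of 16 rose, 2 fell and 1 did not pass (camera adjusted p = 1.2e-06, adjusted p = 0.0166 with an estimated correlation), with the sensors Nlrp3 (5.67 ± 0.08) and Mefv (6.09 ± 0.17). Of apoptosis regulators, 14 of 22 rose, 3 fell and 5 did not pass (camera adjusted p = 6.2e-05, adjusted p = 0.00978 with an estimated correlation). Both Bcl2a1a, which protects from apoptosis (6.28 ± 0.27), and the death receptor gene Fas (4.79 ± 0.11) rose. Adjusted over the list alone, these counts were the same apart from 22 higher and 1 lower in the chemokine list.

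Cell cycle genes fell with HKCA in Lyz2Cre, though neither call was kept with an estimated correlation. Of S-phase genes, 5 of 25 rose, 19 fell and 1 did not pass (camera adjusted p = 0.00803, adjusted p = 0.235 with an estimated correlation), and the helicase gene Mcm2 was one of those that fell (-2.05 ± 0.10). Of G2 and mitosis genes, 3 of 29 rose, 19 fell and 7 did not pass (camera adjusted p = 0.00540, adjusted p = 0.259 with an estimated correlation). The centromere gene Cenpa fell (-2.30 ± 0.11), while the proliferation marker Mki67 (1.56 ± 0.06) and the spindle gene Tpx2 (2.31 ± 0.07) rose. The numbers adjusted over the list alone were the same.

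In Lyz2Cre:KLF6 Fl/Fl with HKCA, Cxcl10 (12.44 ± 0.18), Nos2 (12.32 ± 0.32), Ifi205 (11.95 ± 0.13) and Il1b (11.34 ± 0.38) rose, and Il6 went from 4.43 ± 1.70 to 15430 ± 445 normalised counts (SD, n = 3). Cnr2 (-6.84 ± 0.23), Bmf (-5.39 ± 0.23) and Sesn1 (-5.24 ± 0.10) fell. Of all genes, 12093 of 19440 genes tested passed (6077 higher, 6016 lower). At least 2-fold changes made up 6122 of them (3285 higher, 2837 lower). With a common sum the split was 2938 higher and 11443 lower, and with quantile normalisation 4855 higher and 7342 lower. By list, 20 of 40 passed. The type I interferon-stimulated list again rose throughout, as 33 of 33 rose, 0 fell and 0 did not pass (camera adjusted p = 7.1e-26, adjusted p = 0.0544 with an estimated correlation). Of G2 and mitosis genes, 2 of 29 rose, 24 fell and 3 did not pass (camera adjusted p = 3.5e-06, adjusted p = 0.0895 with an estimated correlation), and neither call was kept. These counts were, adjusted over the list alone, the same. Averaged over both genotypes, 13723 genes passed (6785 higher, 6938 lower, against 3332 higher and 12112 lower with a common sum), and so did 22 lists. Replicate 1 of HKCA-treated Lyz2Cre stood apart from replicates 2 and 3: its chi-square per degree of freedom against them was 25.4 and 21.5, against 5.63 between those. Without it, 12041 genes passed for HKCA in Lyz2Cre.

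Set directly against scleroglucan in Lyz2Cre, HKCA gave higher interferon-related genes and lower NRF2 targets. Cxcl11 was at 3685 ± 262 normalised counts (SD, n = 3) with HKCA and 0.80 ± 0.755 with scleroglucan, and Il12b at 2434 ± 164 and 1.03 ± 1.11. Cxcl10 (10.31 ± 0.18), Nos2 (9.80 ± 0.32) and Mx1 (9.48 ± 0.18) were higher with HKCA, as was Iigp1, an immunity-related GTPase gene (9.45 ± 0.24). Cnr2 (-5.98 ± 0.23), the iron exporter gene Slc40a1 (-5.12 ± 0.11) and the secreted phospholipase gene Pla2g5 (-4.68 ± 0.37) were lower. Of all genes, 11072 of 19440 genes tested passed (5459 higher, 5613 lower). Changes of 2-fold or more accounted for 5007 of them (2622 higher, 2385 lower). The split was 2631 higher and 10834 lower with a common sum and 4333 higher and 6750 lower with quantile normalisation. Of NRF2 targets, 0 of 19 were higher, 18 lower and 1 did not pass (camera adjusted p = 7.6e-11, adjusted p = 0.0317 with an estimated correlation). Srxn1 (-3.48 ± 0.07), Gclc (-3.39 ± 0.06), Nqo1 (-3.31 ± 0.12) and Hmox1 (-2.26 ± 0.06) were among the lower ones. In the type I interferon-stimulated list, 33 of 33 were higher, 0 lower and 0 did not pass (camera adjusted p = 3.1e-31, adjusted p = 0.0364 with an estimated correlation). Of class I presentation genes, 13 of 13 were higher, 0 lower and 0 did not pass (camera adjusted p = 2.1e-11, adjusted p = 0.0483 with an estimated correlation). Adjusted over the list alone, these counts were the same. Klf6 was 1.67 ± 0.04 higher with HKCA than with scleroglucan.

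The scleroglucan and HKCA responses of Lyz2Cre overlapped. 2913 genes were higher with both and 2679 lower with both, 5592 in all, where independent lists of these sizes would share 1319 and 1279, and 1279 genes moved in opposite directions. Both responses use the same 3 untreated libraries, which alone gives a correlation. Across genes, which are not independent replicates, Pearson's r of the fold changes was 0.563 and their covariance 0.734. In 20 simulations with no response and shared untreated libraries, r averaged 0.502 (0.480 to 0.524), covariance averaged 0.0623 (at most 0.0652), and no simulation shared more than 0 called genes. The covariance was far above what shared libraries give. The simulated r and shared calls come from libraries with no response, in which hardly any gene is called. They cannot show how much of the observed r or of the shared calls the shared libraries give.

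Before any stimulus, Lyz2Cre:KLF6 Fl/Fl macrophages had higher interferon-stimulated and cell cycle genes and lower cholesterol synthesis genes than Lyz2Cre. Slc13a3, a dicarboxylate transporter gene, was at 156 ± 17.2 normalised counts (SD, n = 3) against 1.83 ± 0.764, and the interferon-inducible Ifi213 at 88.8 ± 10.8 against 2.23 ± 2.31. Arg1, the arginase of alternatively activated macrophages, was at 48.2 ± 21.8 against 2.73 ± 2.50, and Pkp3, a desmosomal plakophilin, at 42.6 ± 2.82 against 0.667 ± 0.577. Calm4, a calmodulin-like gene, was at 18.5 ± 2.77 and listed at 0 in Lyz2Cre. Nptx1, a neuronal pentraxin gene (4.83 ± 0.24), and Oasl1, an interferon-induced gene (4.07 ± 0.16), were also higher. The lower genes included Smoc2, a matrix protein (-2.83 ± 0.34), the peptide transporter gene Slc15a2 (-2.52 ± 0.12), the ubiquitin ligase gene Trim36 (-2.50 ± 0.11) and the chemokine gene Ccl28 (-2.44 ± 0.43). Of all genes, 5314 of 19440 genes tested passed (2467 higher, 2847 lower). At least 2-fold changes made up 1077 of them (897 higher, 180 lower). The split was 4069 higher and 1764 lower with a common sum and 3048 higher and 2277 lower with a common upper quartile.

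Of the 40 lists, 19 differed between the untreated genotypes. Of type I interferon-stimulated genes, 32 of 33 were higher, 0 lower and 1 did not pass (camera adjusted p = 1.5e-41, adjusted p = 0.0199 with an estimated correlation). Ifi44 (3.97 ± 0.19), Mx1 (3.31 ± 0.18) and the transcription factor gene Irf7 (2.66 ± 0.15) were among them. Guanylate-binding protein and immunity-related GTPase genes were higher too: 15 of 17 were higher, 0 lower and 2 did not pass (camera adjusted p = 1.3e-15, adjusted p = 0.00727 with an estimated correlation). Iigp1 was higher (4.06 ± 0.24), and Gbp4 was at 29.9 ± 9.87 normalised counts against 1.33 ± 1.16. Of G2 and mitosis genes, 27 of 29 were higher, 0 lower and 2 did not pass (camera adjusted p = 6.2e-20, adjusted p = 0.00727 with an estimated correlation), such as the spindle checkpoint gene Bub1 (1.34 ± 0.14) and Mki67 (1.20 ± 0.06). Of S-phase genes, 23 of 25 were higher, 0 lower and 2 did not pass (camera adjusted p = 2.8e-16, adjusted p = 0.00727 with an estimated correlation). The ribonucleotide reductase gene Rrm2 (1.35 ± 0.10) and the helicase gene Mcm5 (1.15 ± 0.08) were higher. Cholesterol synthesis and uptake genes were lower: 0 of 22 were higher, 19 lower and 3 did not pass (camera adjusted p = 1.0e-16, adjusted p = 0.00727 with an estimated correlation). They included Hmgcs1 (-1.13 ± 0.08). Of ribosomal protein genes, 36 of 56 were higher, 0 lower and 20 did not pass (camera adjusted p = 4.6e-11, adjusted p = 0.0411 with an estimated correlation). Of NRF2 targets, 0 of 19 were higher, 11 lower and 8 did not pass (camera adjusted p = 5.5e-07, adjusted p = 0.0801 with an estimated correlation). The glutathione genes Gsr (-1.03 ± 0.06) and Gclm (-0.99 ± 0.06) were lower. The numbers adjusted over the list alone were the same apart from 28 higher and 0 lower in the G2 and mitosis list, 40 higher and 0 lower in the ribosomal list and 0 higher and 12 lower in the NRF2 list.

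Inflammatory cytokine genes went both ways in untreated Lyz2Cre:KLF6 Fl/Fl. Tnf was higher (0.98 ± 0.07). Il1b was at 16.4 ± 12.7 normalised counts (SD, n = 3) against 3.67 ± 0.586, a difference of 1.53 ± 0.38 (adjusted p = 0.00389). Its 3 values overlapped those of Lyz2Cre, and the Il1b difference was 2.31 without replicate 1 of untreated Lyz2Cre:KLF6 Fl/Fl and 0.96 without replicate 2. It did not pass when only these 6 libraries were fitted (adjusted p = 0.155, the highest over its alternatives, with 5.3e-08 the lowest). Of NF-kB feedback and inflammatory cytokine genes, 12 of 30 were higher, 7 lower and 11 did not pass (camera adjusted p = 0.0473, adjusted p = 0.564 with an estimated correlation). Klf2, another gene of the family, was higher (1.14 ± 0.12) and Mrc1 lower (-0.67 ± 0.05). Markers of other cells moved as well. Of neutrophil and granulocyte markers, 4 of 10 were higher, 0 lower and 6 did not pass (camera adjusted p = 0.0194, adjusted p = 0.182 with an estimated correlation), with S100a9 at 17.5 ± 3.31 normalised counts against 3.57 ± 1.99. The B cell receptor gene Cd79b was at 62.2 ± 11.6 against 5.37 ± 2.27. These counts were, adjusted over the list alone, the same apart from 13 higher and 7 lower in the NF-kB list.

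With scleroglucan, the difference between the genotypes was in inflammatory and oxidative defence genes, which were lower in Lyz2Cre:KLF6 Fl/Fl, and in cell cycle genes, which were higher. Tarm1 (-3.43 ± 0.29), Cxcl3 (-3.19 ± 0.22), Aoah, which inactivates lipopolysaccharide (-3.15 ± 0.07), and Tnfsf4, the OX40 ligand (-2.93 ± 0.23), were lower. Aoah was lower untreated (-2.33) and with HKCA (-1.10) as well. The eosinophil chemokine gene Ccl24 was at 0.767 ± 1.33 normalised counts (SD, n = 3) against 18.1 ± 6.09 in Lyz2Cre. Higher genes included Pkp3 (36.5 ± 6.15 against 0.533 ± 0.473) and Calm4 (22.9 ± 2.78, listed at 0 in Lyz2Cre). Of all genes, 5914 of 19440 genes tested passed (2831 higher, 3083 lower). Changes of 2-fold or more accounted for 1165 of them (782 higher, 383 lower). All called genes together turned to a majority of higher ones with a common sum (5084 higher and 1782 lower), a common upper quartile (3187 higher and 2769 lower) and quantile normalisation (3250 higher and 2887 lower).

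Between the scleroglucan-treated genotypes, 19 of 40 lists differed. Of NF-kB feedback and inflammatory cytokine genes, 0 of 30 were higher, 22 lower and 8 did not pass (camera adjusted p = 5.8e-16, adjusted p = 0.0327 with an estimated correlation). Il1b (-2.33 ± 0.38), Ptgs2 (-1.30 ± 0.15) and Tnf (-1.27 ± 0.07) were lower. NRF2 targets were lower too: 0 of 19 were higher, 17 lower and 2 did not pass (camera adjusted p = 6.0e-17, adjusted p = 0.0120 with an estimated correlation). Slc7a11 (-1.56 ± 0.10) and Hmox1 (-0.82 ± 0.06) were among them. Of interleukin-10 and feedback inhibitor genes, 1 of 21 were higher, 16 lower and 4 did not pass (camera adjusted p = 7.3e-09, adjusted p = 0.0657 with an estimated correlation). Il10 (-1.14 ± 0.15) and the cytokine signalling inhibitor gene Socs3 (-1.25 ± 0.06) were lower. Of apoptosis regulators, 3 of 22 were higher, 10 lower and 9 did not pass (camera adjusted p = 0.00198, adjusted p = 0.0225 with an estimated correlation). Both the protective Bcl2a1d (-1.62 ± 0.24) and the death receptor gene Fas (-1.15 ± 0.11) were lower. Of inflammasome genes, 1 of 16 were higher, 8 lower and 7 did not pass (camera adjusted p = 0.00200, adjusted p = 0.120 with an estimated correlation), and the caspase gene Casp4 was lower (-2.39 ± 0.07). G2 and mitosis genes, with Bub1 (1.69 ± 0.14), were higher: 28 of 29 were higher, 0 lower and 1 did not pass (camera adjusted p = 4.2e-21, adjusted p = 0.00539 with an estimated correlation). S-phase genes, with Cdc6 (1.80 ± 0.28), were higher as well: 25 of 25 were higher, 0 lower and 0 did not pass (camera adjusted p = 1.7e-18, adjusted p = 0.00517 with an estimated correlation). The type I interferon-stimulated list stayed higher, as 27 of 33 were higher, 2 lower and 4 did not pass (camera adjusted p = 1.7e-18, adjusted p = 0.133 with an estimated correlation). Oasl1 (2.76 ± 0.16) and Ifi44 (2.39 ± 0.19) were among the higher ones. Adjusted over the list alone, these counts were the same apart from 1 higher and 22 lower in the NF-kB list, 1 higher and 17 lower in the interleukin-10 list, 3 higher and 11 lower in the apoptosis list, 29 higher and 0 lower in the G2 and mitosis list and 28 higher and 2 lower in the interferon-stimulated list.

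With HKCA, 33.0% of the genes tested differed between the genotypes, against 27.3% untreated and 30.4% with scleroglucan. Nos2 and 16 of the 30 NF-kB list genes did not pass. Nptx1 (4.59 ± 0.24) was higher in Lyz2Cre:KLF6 Fl/Fl, as was Pkp3 (31.5 ± 5.23 normalised counts against 0.433 ± 0.751, SD, n = 3). The inhibitory receptor gene Pirb (-2.71 ± 0.05), the myeloid differentiation marker gene Myadm (-2.82 ± 0.05) and Trim36 (-3.01 ± 0.11) were lower. Ccl24 was at 6.43 ± 1.44 normalised counts against 59.5 ± 13.7, and the zinc finger gene Zfp536 at 2.80 ± 1.74 against 54.7 ± 15.4. The interleukin-1 genes Il1a (-1.35 ± 0.11) and Il1b (-1.34 ± 0.38) were lower and Ccl2, a monocyte chemokine gene (1.45 ± 0.11), higher. The Il1b call was lost with eBayes without trend (adjusted p = 0.0525, the highest over its alternatives, with 9.2e-11 the lowest). Nos2 did not pass (0.28 ± 0.32), though it was called in edgeR (adjusted p = 0.0276, with 0.0150 to 0.669 over its alternatives). Of all genes, 6422 of 19440 genes tested passed (3184 higher, 3238 lower). At least 2-fold changes made up 1295 of them (974 higher, 321 lower). All called genes split into 3430 higher and 2819 lower with a common sum and 3565 higher and 2890 lower with a common upper quartile. Without replicate 1 of HKCA-treated Lyz2Cre, 6395 passed.

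Of the 40 lists, 17 differed between the HKCA-treated genotypes, and 0 of these calls were kept with an estimated correlation. Cholesterol synthesis and uptake genes were lower: 0 of 22 were higher, 18 lower and 4 did not pass (camera adjusted p = 2.8e-13, adjusted p = 0.0622 with an estimated correlation). Hmgcs1 (-1.19 ± 0.08) was among them. Of S-phase genes, 18 of 25 were higher, 1 lower and 6 did not pass (camera adjusted p = 4.9e-06, adjusted p = 0.136 with an estimated correlation). Cdc6 was higher (0.96 ± 0.28), but the call was lost without replicate 2 of HKCA-treated Lyz2Cre (0.65, adjusted p = 0.0740) and in edgeR (adjusted p = 0.0556). Its adjusted p ran from 2.5e-04 to 0.114 over the alternatives. Ccne1, which encodes cyclin E, was lower (-1.04 ± 0.12). Of hypoxia and HIF-1 targets, 6 of 28 were higher, 13 lower and 9 did not pass (camera adjusted p = 0.0127, adjusted p = 0.398 with an estimated correlation). The stress-response genes Ndrg1 (-1.47 ± 0.07) and Ddit4 (-0.87 ± 0.14) were lower. For type I interferon-stimulated genes, 13 of 33 were higher, 1 lower and 19 did not pass (camera adjusted p = 8.9e-04, adjusted p = 0.568 with an estimated correlation). For NF-kB feedback and inflammatory cytokine genes, 2 of 30 were higher, 12 lower and 16 did not pass (camera adjusted p = 0.0447, adjusted p = 0.584 with an estimated correlation). For T, NK and B lymphocyte markers, 6 of 20 were higher, 1 lower and 13 did not pass (camera adjusted p = 0.0439, adjusted p = 0.388 with an estimated correlation). The numbers adjusted over the list alone were the same apart from 6 higher and 14 lower in the hypoxia list and 15 higher and 1 lower in the interferon-stimulated list.

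**Figure D2:**
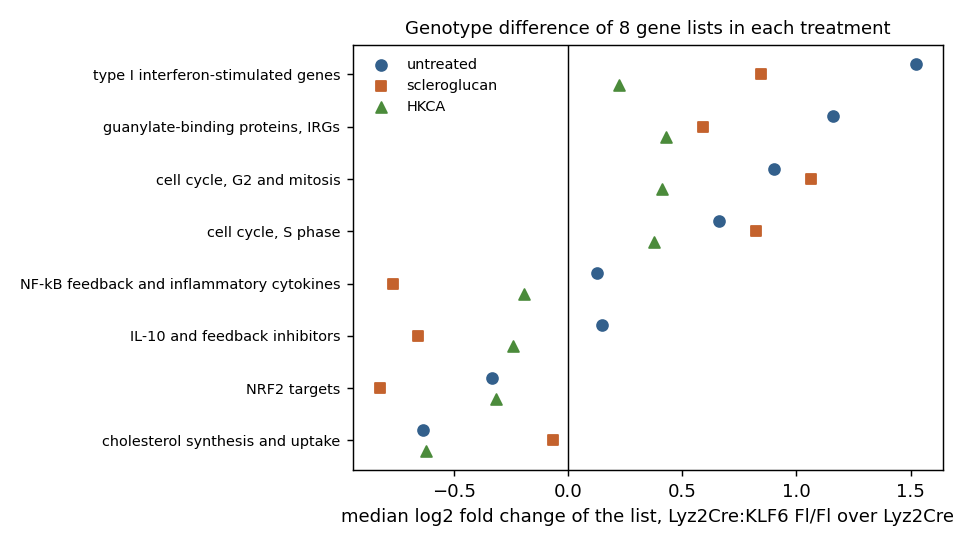
Median log2 fold change of 8 gene lists, Lyz2Cre:KLF6 Fl/Fl over Lyz2Cre (horizontal axis), in untreated (circles), scleroglucan-treated (squares) and HKCA-treated macrophages (triangles). The type I interferon-stimulated list has medians of 1.52, 0.85 and 0.22, and the NF-kB list 0.13, -0.76 and -0.19.

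Averaged over the 3 treatments, 8600 genes differed between the genotypes (4341 higher, 4259 lower, against 6356 higher and 2812 lower with a common sum), 1043 of them by at least 2-fold (879 higher, 164 lower). Smoc2 (-2.86 ± 0.19) and Pirb (-2.36 ± 0.03) were among the lower genes. Of the 40 lists, 14 differed. Of G2 and mitosis genes, 29 of 29 were higher, 0 lower and 0 did not pass (camera adjusted p = 6.2e-17, adjusted p = 0.0143 with an estimated correlation). Of NRF2 targets, 0 of 19 were higher, 16 lower and 3 did not pass (camera adjusted p = 6.4e-11, adjusted p = 0.0451 with an estimated correlation). These counts were, adjusted over the list alone, the same.

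The genotype differences of the 3 treatments share no libraries, and they overlapped: 3157 genes differed in the same direction untreated and with scleroglucan (240 in opposite directions), 2944 untreated and with HKCA (329 opposite), and 3495 with scleroglucan and with HKCA (272 opposite). Independent lists would share 359 higher and 452 lower genes for the untreated and scleroglucan pair, 404 and 474 for the untreated and HKCA pair, and 464 and 514 for the stimulated pair. Across genes, which are not independent replicates, r was 0.555, 0.447 and 0.499.

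Genes beside the floxed locus were examined because an engineered allele can carry flanking DNA of another strain. Of 81 genes tested within 10 Mb of Klf6, 35 differed untreated (43.2% against 27.3% elsewhere), 30 with scleroglucan (37.0% against 30.4%), 29 with HKCA (35.8% against 33.0%) and 38 over the 3 treatments (46.9% against 44.2%). At least 2-fold differences were found in 14 of them untreated (17.3% against 5.49% elsewhere), 11 with scleroglucan (13.6% against 5.96%), 14 with HKCA (17.3% against 6.62%) and 13 of 81 over the 3 treatments (against 5.32%). As a set they showed no shift in 1 direction that passed (camera adjusted p = 0.398 untreated and 0.317 in each of the others), but this test decides little, as members went both ways (16 higher and 19 lower untreated).

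The response to scleroglucan was smaller in Lyz2Cre:KLF6 Fl/Fl. Of 4641 genes that rose in the average of both genotypes, 74.6% rose less in Lyz2Cre:KLF6 Fl/Fl. The median response was 0.38 against 0.57 (67.0%), and the median of the differences was -0.161 (permutation p = 0.0150, 400 arrangements, two-sided). Of 4512 genes that fell, 78.2% fell less. Their median response was 0.32 against 0.50 in size (63.9%), and the median of the differences was -0.164 (permutation p = 0.00500, the smallest possible). With a common sum this test did not pass (-0.182, permutation p = 0.10). In simulated data, drawn only once for each size, the permutation p was similar for a smaller and an equal response. So few runs do not show what the test can tell apart, and its p is read with caution beside the size of the difference. Among single genes, the difference in response passed for 1968 (871 higher, 1097 lower). The cytokine genes Il1b (-3.86 ± 0.54) and Tnf (-2.25 ± 0.10), the chemokine gene Cxcl2 (-3.47 ± 0.33), Gbp5 (-3.85 ± 0.37) and the acute-phase gene Saa3 (-2.86 ± 0.54) responded less. The Il1b value includes its difference between the untreated genotypes (1.53), whose libraries overlapped. That difference did not pass in limma when only the untreated libraries were fitted (adjusted p = 0.155). Rasgrp3 (2.39 ± 0.24) and Dkk2 (2.17 ± 0.46), which scleroglucan lowered in Lyz2Cre, fell less. With a common sum the split was 1203 higher and 979 lower.

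**Figure D3:**
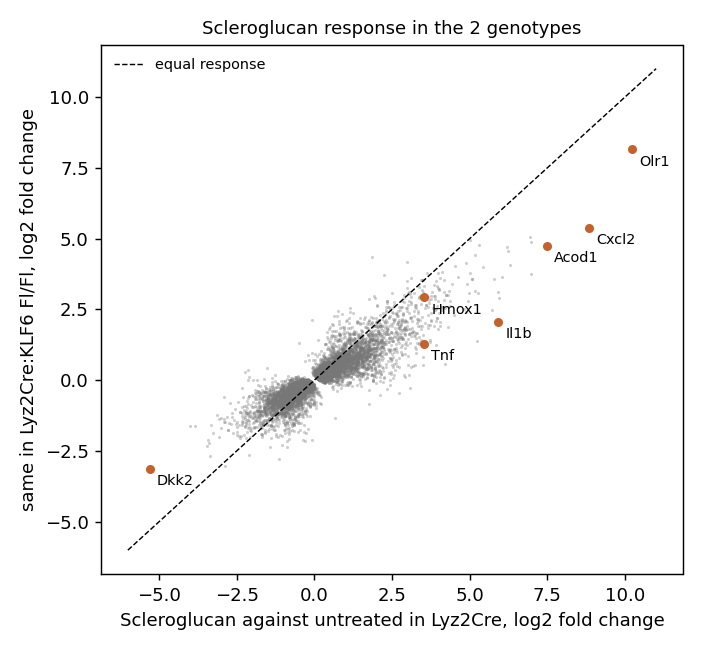
Scleroglucan response in Lyz2Cre (horizontal axis) and in Lyz2Cre:KLF6 Fl/Fl (vertical axis), in log2 fold change over untreated, where each grey point is 1 of the 9153 genes that passed in the mean of both genotypes, orange points are named genes, and the dashed line marks equal responses. Il1b lies at 5.92 and 2.06, under the line, and its untreated values overlapped between the genotypes.

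By list, 20 of 40 differed in their scleroglucan response, 18 of them lower in Lyz2Cre:KLF6 Fl/Fl. Higher and lower refer here to the fold change over untreated cells. Of NF-kB feedback and inflammatory cytokine genes, 0 of 30 were higher, 21 lower and 9 did not pass (camera adjusted p = 1.2e-32, adjusted p = 0.00458 with an estimated correlation). Of the chemokines, 0 of 23 were higher, 14 lower and 9 did not pass (camera adjusted p = 2.2e-14, adjusted p = 0.00230 with an estimated correlation). Of type I interferon-stimulated genes, 0 of 33 were higher, 25 lower and 8 did not pass (camera adjusted p = 2.2e-23, adjusted p = 0.0431 with an estimated correlation). Most of this list began higher in untreated Lyz2Cre:KLF6 Fl/Fl and stayed higher there with scleroglucan. NRF2 targets responded less, as 0 of 19 were higher, 9 lower and 10 did not pass (camera adjusted p = 1.1e-08, adjusted p = 0.0325 with an estimated correlation). Class I presentation genes did too: 0 of 13 were higher, 9 lower and 4 did not pass (camera adjusted p = 4.4e-15, adjusted p = 0.0191 with an estimated correlation). Cholesterol synthesis and uptake genes, most of them lower in untreated Lyz2Cre:KLF6 Fl/Fl, had higher fold changes: 16 of 22 were higher, 0 lower and 6 did not pass (camera adjusted p = 1.3e-18, adjusted p = 0.00626 with an estimated correlation). Liver X receptor targets and fatty acid synthesis genes did too: 10 of 20 were higher, 2 lower and 8 did not pass (camera adjusted p = 1.3e-05, adjusted p = 0.0187 with an estimated correlation). In Lyz2Cre, scleroglucan lowered more genes of both lists than it raised. For a gene that fell there, a higher value is a smaller fall or a rise, not a larger response. Adjusted over the list alone, these counts were 0 higher and 22 lower in the NF-kB list, 0 higher and 16 lower in the chemokine list, 0 higher and 28 lower in the interferon-stimulated list, 0 higher and 10 lower in the NRF2 list, 0 higher and 11 lower in the class I presentation list, 19 higher and 0 lower in the cholesterol list and 12 higher and 3 lower in the liver X receptor list. Idi1, an isoprenoid isomerase gene of the cholesterol list, had 1.21 ± 0.35 (adjusted p = 0.0253, and 0.00727 to 0.0766 over the alternatives). Its call was lost on leaving out any of 7 libraries. The value was 1.20 without Lyz2Cre untreated replicate 1, 1.19 without Lyz2Cre untreated replicate 3, 1.10 without Lyz2Cre:KLF6 Fl/Fl untreated replicate 3, 1.10 without Lyz2Cre scleroglucan replicate 1, 1.09 without Lyz2Cre scleroglucan replicate 3, 1.12 without Lyz2Cre:KLF6 Fl/Fl scleroglucan replicate 2 and 1.06 without Lyz2Cre:KLF6 Fl/Fl scleroglucan replicate 3.

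The response to HKCA differed between the genotypes for 14.6% of the genes tested, against 10.1% for scleroglucan, while 0 list calls were kept with an estimated correlation. Ifi213 (-4.06 ± 0.40), with 2.23 ± 2.31 normalised counts in untreated Lyz2Cre (SD, n = 3), rose by less in Lyz2Cre:KLF6 Fl/Fl, as did Oasl1 (-3.21 ± 0.23) and Ifi44 (-3.09 ± 0.27). These genes began higher in untreated Lyz2Cre:KLF6 Fl/Fl. Arg1 (-3.82 ± 0.58), with 2.73 ± 2.50 in untreated Lyz2Cre, Saa3 (-3.74 ± 0.54) and Il1b (-2.87 ± 0.54) also responded less, and Ccl2 (1.55 ± 0.15) more. Arg1 and Il1b began higher in untreated Lyz2Cre:KLF6 Fl/Fl too. For Il1b that difference (1.53) is part of the value, and it did not pass when only the untreated libraries were fitted. The rise of Klf6 itself was smaller (-0.21 ± 0.06, adjusted p = 0.0192). This call was lost without replicate 3 of untreated Lyz2Cre (-0.20, adjusted p = 0.0514), with eBayes without trend (adjusted p = 0.0554, the highest over its alternatives, with 0.00120 the lowest) and in edgeR with TMM factors (adjusted p = 0.0525). In all, 2836 genes passed (1378 higher, 1458 lower, against 909 higher and 2039 lower with a common sum). Of 6785 genes that HKCA raised, 52.0% rose less in Lyz2Cre:KLF6 Fl/Fl. The median difference was -0.0144, with the median response at 97.9% of that in Lyz2Cre (permutation p = 0.260). Of 6938 that it lowered, 55.7% fell less. Their median difference was -0.0454, with the median at 94.9% (permutation p = 0.00500), and it turned to 0.0528 with a common sum (permutation p = 0.230).

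Of the 40 lists, 21 differed in their HKCA response, 19 of them lower in Lyz2Cre:KLF6 Fl/Fl, and 0 of these calls were kept with an estimated correlation. Higher and lower refer here to the fold change over untreated cells. In the type I interferon-stimulated list, 0 of 33 were higher, 30 lower and 3 did not pass (camera adjusted p = 1.1e-39, adjusted p = 0.0605 with an estimated correlation). Most of this list began higher in untreated Lyz2Cre:KLF6 Fl/Fl. Between the HKCA-treated genotypes most of it did not pass, and more of it was higher in Lyz2Cre:KLF6 Fl/Fl than lower. Of guanylate-binding protein and immunity-related GTPase genes, 1 of 17 were higher, 14 lower and 2 did not pass (camera adjusted p = 4.3e-10, adjusted p = 0.0605 with an estimated correlation). Of G2 and mitosis genes, 0 of 29 were higher, 9 lower and 20 did not pass (camera adjusted p = 3.1e-08, adjusted p = 0.0743 with an estimated correlation). For a gene that fell with HKCA, as most of this list did in both genotypes, lower means a larger fall. Heat shock and dissociation stress genes had higher fold changes: 4 of 12 were higher, 0 lower and 8 did not pass (camera adjusted p = 0.00492, adjusted p = 0.0639 with an estimated correlation). The numbers adjusted over the list alone were the same apart from 0 higher and 31 lower in the interferon-stimulated list, 0 higher and 10 lower in the G2 and mitosis list and 5 higher and 0 lower in the heat shock list. In no comparison did a call reach arachidonic acid metabolism genes (lowest camera adjusted p = 0.130), dendritic cell markers (adjusted p = 0.0586), erythroid and megakaryocyte markers (adjusted p = 0.218) or mast cell and basophil markers (adjusted p = 0.120).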

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

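No test in this part was chosen only after its result was seen, but the genes named in it were picked from the results. The response to scleroglucan differed between the genotypes for 1968 genes and 20 of 40 lists, by the test of the interaction in limma. Among named genes the differences were -3.86 for Il1b, -3.85 for Gbp5, -3.47 for Cxcl2, -2.25 for Tnf, -2.86 for Saa3, 2.39 for Rasgrp3, 2.17 for Dkk2 and 1.21 for Idi1, all log2 values. The Il1b value holds an untreated difference that did not pass when only the untreated libraries were fitted. The median response differed by -0.161 among genes that rose and by -0.164 among genes that fell. In simulated data, the permutation of genotype labels gave a similar p for a smaller and an equal response, but each was drawn only once, too few to judge the test. Other splits of the 12 libraries into genotypes do not exclude chance for the number of genes: 7 of 100 splits, the real one included, called as many as 1968, and the highest other called 3249. All 6 of the other splits that did so kept the genotypes whole in the untreated or in the scleroglucan-treated libraries, so that they carry the difference between the genotypes. Splits that mixed the genotypes in both called at most 0.

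The response to HKCA differed between the genotypes for 2836 genes and 21 of 40 lists by the same test. Among named genes the differences were -0.21 for Klf6, -4.06 for Ifi213, -3.82 for Arg1, -3.74 for Saa3, -3.21 for Oasl1, -3.09 for Ifi44, -2.87 for Il1b and 1.55 for Ccl2. The Il1b value again holds its uncertain untreated difference. Among genes that fell with HKCA, the median response differed by -0.0454, which depended on the scaling of the libraries. Chance was not excluded by the splits for the number of genes here either: 5 of 100 called as many as 2836, with 7459 the highest other. The other 4 splits of that size again kept the genotypes whole in at least 1 treatment, and splits that mixed them in both called at most 0.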

How the results depend on the processing

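Of the alternatives, a filter at a mean of 10 and edgeR with TMM factors were chosen only after the results were seen. Among the main counts and responses, 663 alternative values stayed near the reported ones or on the same side of their test, 27 moved, 3 lost their call and 1 turned its direction. Among single named genes, 3565 stayed, 15 lost a call, 8 gained one and 0 reversed. The cause of each move was not tested, except that fewer genes pass a fold minimum by construction. With a correlation estimated from the data, the lists called were 7 of 20 for scleroglucan in Lyz2Cre, 4 of 16 for scleroglucan in Lyz2Cre:KLF6 Fl/Fl, 5 of 20 for scleroglucan in the mean of both, 9 of 24 for HKCA in Lyz2Cre, 6 of 20 for HKCA in Lyz2Cre:KLF6 Fl/Fl, 7 of 22 for HKCA in the mean of both, 9 of 18 for HKCA against scleroglucan, 6 of 19 for the untreated genotypes, 5 of 19 for the genotypes with scleroglucan, 0 of 17 for the genotypes with HKCA, 4 of 14 for the genotypes over 3 treatments, 15 of 20 for the scleroglucan interaction and 0 of 21 for the HKCA interaction. Genes changed by at least 2-fold numbered 2292 for scleroglucan in Lyz2Cre, 1160 for scleroglucan in Lyz2Cre:KLF6 Fl/Fl, 1838 for scleroglucan in the mean of both, 6303 for HKCA in Lyz2Cre, 6122 for HKCA in Lyz2Cre:KLF6 Fl/Fl, 6481 for HKCA in the mean of both, 5007 for HKCA against scleroglucan, 1077 for the untreated genotypes, 1165 for the genotypes with scleroglucan, 1295 for the genotypes with HKCA and 1043 for the genotypes over 3 treatments. Overlaps in the same direction at 2-fold were 1510 for the 2 stimuli in Lyz2Cre, 504 for the genotypes untreated and with scleroglucan, 411 for the genotypes untreated and with HKCA and 445 for the genotypes under the 2 stimuli. Among genes that fell with HKCA, the median difference in response was -0.0205 with a common upper quartile (permutation p = 0.455), -0.00778 with quantile normalisation (permutation p = 0.530) and, reversed, 0.0528 with a common sum (permutation p = 0.230). Among genes that fell with scleroglucan it was -0.182 with a common sum (permutation p = 0.10). The median of all genes in comparisons of HKCA with other treatments moved to between -0.17 and -0.15 with a common upper quartile, -0.17 and -0.14 with quantile normalisation, and -0.72 and -0.60 with a common sum. With a common sum it also moved to 0.11 between the untreated genotypes and 0.13 between those with scleroglucan. Of the genes called in limma, 89.5% to 99.2% were also called in edgeR with the deposited size factors, all in the same direction. Leaving out 1 library gave 7293 to 7578 genes for scleroglucan in Lyz2Cre, 4844 to 5186 in Lyz2Cre:KLF6 Fl/Fl, 11647 to 12041 and 11429 to 11546 for HKCA, 4313 to 4827, 4959 to 5199 and 5644 to 6395 between the genotypes untreated, with scleroglucan and with HKCA, and 1532 to 1862 and 2279 to 3200 for the interactions. With the replicate number as a block (replicate block), the genes called were 8174 for scleroglucan in Lyz2Cre, 5741 for scleroglucan in Lyz2Cre:KLF6 Fl/Fl, 9093 for scleroglucan in the mean of both, 12253 for HKCA in Lyz2Cre, 12068 for HKCA in Lyz2Cre:KLF6 Fl/Fl, 13747 for HKCA in the mean of both, 11052 for HKCA against scleroglucan, 5316 for the untreated genotypes, 5880 for the genotypes with scleroglucan, 6403 for the genotypes with HKCA, 8573 for the genotypes over 3 treatments, 1970 for the scleroglucan interaction and 2782 for the HKCA interaction.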

Other observations

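The tests chosen only after the result was seen were those on chromosome windows, on genes near Klf6, on pseudogenes, on the untreated level of the scleroglucan genes, on scaling for those that fell, on markers of other cells and on the chromosomes of interferon-stimulated genes. For the 8 comparisons of 3 libraries with 3, the 10 splits are too few for a share under 0.05, and in each only 1 of 10, the real one, called as many genes. The real value and the highest other were 8218 genes against 2 for scleroglucan in Lyz2Cre, 5780 genes against 0 in Lyz2Cre:KLF6 Fl/Fl, 12289 genes against 1 for HKCA in Lyz2Cre, 12093 genes against 1 in Lyz2Cre:KLF6 Fl/Fl, 11072 genes against 1 for HKCA against scleroglucan, and 5314 genes against 1, 5914 genes against 0 and 6422 genes against 4 between the genotypes untreated, with scleroglucan and with HKCA. For the means over groups, only 1 of 100 splits, the real one, called as many, which excludes a chance split of the libraries: 9153 genes against 5930 for scleroglucan, 13723 genes against 9182 for HKCA and 8600 genes against 3073 for the genotypes.

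294 genes differed between the genotypes by at least 2-fold in every treatment, 247 of them higher in Lyz2Cre:KLF6 Fl/Fl. Inherited chromosome segments that differ between the mouse lines may account for a part of them: 4 windows of 10 Mb were crowded with such genes, where 1000 shuffles of positions gave at most 2, but these windows held 28 genes, 9.52% of the total. One of them holds Klf6 and another holds histone genes, and without histones 5 windows with 27 genes were crowded, against at most 1 in shuffles. Of the genes named above, Calm4 lies in the window with Klf6 and Aoah in the one with histone genes. Pirb lies in the window added without histones, on chromosome 7. The shuffles take neighbouring genes as unrelated. Neighbours of the same family, such as Col4a5 and Col4a6 on chromosome X or Pirb and Pira2 on chromosome 7, can also crowd a window. The crowding cannot tell such families from inherited segments. The values argue against DNA around the floxed allele as the whole cause, since 2.72% of the genes lie within 10 Mb of Klf6 (above the 0.423% of all genes with a position), and against reads shared with near-identical copies as the whole cause, since 8.84% are pseudogenes, near the 6.59% of all genes with a position. For the pseudogenes, unnamed loci (21.1% with the pseudogenes, against 24.5%) and families of similar genes among them, shared reads cannot be told apart, and an effect of reduced Klf6 stays open and was not tested.

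The smaller response to scleroglucan in Lyz2Cre:KLF6 Fl/Fl among genes that rose was not accounted for by scaling or by any 1 library: the weakest median shortfall was -0.155 under 3 scalings and -0.145 without any 1 library (without replicate 2 of scleroglucan-treated Lyz2Cre:KLF6 Fl/Fl). Among genes that fell, scaling cannot be told apart, as the shortfall went from -0.164 to -0.182 with a common sum but the permutation p from 0.00500 to 0.10, since more arrangements of the labels then gave a median as large. For genes that rose, a higher untreated level alone would leave about equal levels with scleroglucan. Relative to all genes, their median difference between genotypes was 0.00763 to 0.0470 untreated and -0.149 to -0.124 with scleroglucan over 4 scalings. The untreated median lay between the bounds set in at least 1 scaling and the scleroglucan median in all 4, so by those bounds this cause cannot be told apart. The scleroglucan medians were below 0 in each scaling, which is not the about equal level that a higher untreated level alone would leave. For genes that fell, a different untreated level cannot be told apart. Their median was -0.0799 to -0.0377 untreated, between the bounds set in at least 1 scaling, and 0.0897 to 0.117 with scleroglucan. Differences in the time or dose that reached the cells, a batch shared with genotype and an effect of reduced Klf6 could also give the smaller response and are open, as no label used here gives the first of these and the last was not tested.

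Interferon-stimulated genes were higher in untreated Lyz2Cre:KLF6 Fl/Fl for 32 of 33. One library did not decide this, since at least 31 of the 32 calls stayed without any 1 untreated library (fewest without replicate 1 of untreated Lyz2Cre), and the genes lie on 13 chromosomes, which argues against a few inherited segments as a direct cause. Other cell types in the culture cannot be told apart: the most abundant marker of neutrophils, dendritic cells or lymphocytes that was higher, Csf3r, stood at 3.09% of the macrophage receptor gene Csf1r, above the bound of 1% that would have argued against them, while S100a8 and S100a9, abundant in neutrophils, stood at 0.109% and 0.0572%. Csf3r was at 789 normalised counts in untreated Lyz2Cre and 948 in untreated Lyz2Cre:KLF6 Fl/Fl (0.27 in log2), so much of its level was in both. Among the other markers Il7r (-0.20), Itgax (-0.86), Cd4 (-0.48) and Ighm (-1.44) were lower. Mmp8, Ngp, S100a9, Ccl22, Cd79b, Cd8a, Ncr1 and Trac were higher. Untreated Lyz2Cre had a mean of at least 10 for 3 of the 10 neutrophil, 6 of the 14 dendritic and 3 of the 20 lymphocyte markers, and no sort is given in the labels used here. A difference in batch between the genotypes may be a source too and cannot be told apart from genotype, because 0 libraries have a batch in their labels.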
